A study of Drosophila melanogaster with 4 samples.

How the data were processed

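Chromatin immunoprecipitation and sequencing of H3K4me2 was carried out on nuclei from heads of adult Oregon-R flies raised in population cages with a cycle of 22 days, per the labels' protocols. The chromatin was fixed with formaldehyde, sheared by sonication and precipitated with the antibody. Libraries were grouped by their titles into 2 H3K4me2 ChIP replicates and 2 input DNA replicates. The labels name the input of each replicate as the one that served its region list. No values of the input libraries themselves were used here.

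The authors deposited 3 lists of regions of significant enrichment, per the file headers and source fields, with 1 list for each ChIP replicate and 1 named as a replicate set, called the combined list here. Positions are on FlyBase r5 (release 5), per the file headers, and are counted from 1. Bowtie 0.12.7 is named in the submitters' processing notes. The region caller, its threshold, its minimum width, the treatment of reads that map to many places and the way in which the replicates were combined are not given in the sources used here. Each region carries a score as deposited by the authors, whose definition is likewise not given. The scale of the score was read from the values. Among pairs of replicate 1 regions, 129 differed by 1, the log2 of a ratio of 2, and 156 by the log2 of 3/2, within 1e-09. No pair differed by the natural or decimal logarithm of 2 or of 3/2, and the other lists gave the same picture, so the scores are treated as values on a log2 scale. The scores are used here to describe and rank regions, to correlate the replicates and to compare groups of regions, and no fold enrichment is stated from them. Score and width were related across the regions of a list (Spearman's rho 0.73 in replicate 1 and 0.74 in replicate 2).

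The narrowest region was 1302 bp in replicate 1, 1301 bp in replicate 2 and 1001 bp in the combined list. Sequence lengths were taken from the file headers, which name 14 sequences. Regions were present on 13 of them and on none in the sequence Uextra.

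Overlap between lists was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A region counted as shared where it overlapped the other list by at least 1 bp. Chance overlap came from 1000 random placements of the replicate 1 regions, without overlap among themselves, within their own arm or sequence. Score correlations were taken over regions that overlapped exactly 1 region of the other replicate and were the only region that one overlapped, with 100000 random pairings. Shares of regions carry exact Clopper-Pearson 95% intervals. Sequences were compared by regions per Mb and by the percent of sequence covered, as the mean and SD of the 2 replicates. Comparisons of X with the large autosomal arms used an exact permutation of the 5 arms, a permutation of windows of 1 Mb or, for score differences, 10000 permutations of region pairs. The placement and pairing code was tested on simulated data made from the 5127 replicate 1 regions. A simulated second list in which 90.3% of them were retained gave a shared percentage of 90.3, and a planted X score difference of 0.1 came back as 0.10.

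The main tests, the regions to be named and most alternatives were fixed before the data were examined. Regions named in the text are the 10 widest shared by both replicates, by mean width over regions that paired singly, and the 3 highest-scoring found in only 1 replicate, unless said otherwise. The alternatives were a reciprocal overlap of 50%, the higher-scoring 50% of each list, the 6 chromosome arms alone, circular shifts in place of random placement, merging of regions under 1000 bp apart, scores divided by width, the combined list, and each replicate alone. The limit of 10 kb for wide regions, the tests of X against the autosomal arms, the score differences between replicates by sequence, the windows of 1 Mb and the stretches without regions were added after the data were seen. A gene annotation of release 5 was not used here, and the gene name table at hand belongs to release 6. Positions were not converted between builds, so regions carry no gene names, the 19 gene lists fixed beforehand could not be mapped, and no share of promoters, exons or introns is given.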

Results

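The series maps histone H3 dimethylated at lysine 4 (H3K4me2), a mark found in general at active promoters and enhancers, in nuclei of adult fly heads. The flies were wild-type Oregon-R Drosophila melanogaster, labelled as mixed adults, and heads were separated from whole flies by sieving. Crosslinked chromatin was precipitated with an H3K4me2 antibody and sequenced (ChIP-seq). The 4 libraries form 2 groups, with 2 H3K4me2 ChIP libraries and 2 input DNA libraries. The values analysed here are the regions of significant enrichment of each ChIP replicate and those of a list for both replicates together. The ChIP replicate 1 list held 5127 regions that covered 24.9 Mb, and the replicate 2 list held 5125 regions that covered 25.4 Mb. Median region width was 3658 bp in replicate 1 (quartiles 2452 and 6046 bp) and 3632 bp in replicate 2 (quartiles 2450 and 6206 bp). Nothing in the labels says that the replicates came from separate fly collections, so the spread between them may be technical. Read depth behind the regions is unknown here, and the intervals on shares of regions cover counting error only.

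The first comparison asks where along the chromosomes of head nuclei H3K4me2 lies. The small chromosome 4 was the most densely marked sequence, with 39.5% ± 0.338 (SD, n = 2) of its 1.35 Mb inside regions, against 19.7% ± 0.0708 (SD, n = 2) of the autosomal arms 2L, 2R, 3L and 3R together. Chromosome 4 also had 55.1 ± 0.523 (SD, n = 2) regions per Mb, against 42.3 ± 0.0512 (SD, n = 2) on these arms. Among the large arms, X was covered to 23.7% ± 1.49 (SD, n = 2), 2R to 22.4% ± 0.0127 (SD, n = 2), 3R to 20.4% ± 0.165 (SD, n = 2), 3L to 18.6% ± 0.0224 (SD, n = 2) and 2L to 17.7% ± 0.0615 (SD, n = 2). The order of the autosomal arms was that of their spacing only in part, since 2R had the most regions per Mb (48.9 ± 0.368, SD, n = 2) and 3L the fewest (38.3 ± 0.461, SD, n = 2). The lead of X over 2R differed between the replicates, being 0.266 percentage points in replicate 1 and 2.36 in replicate 2. An exact two-sided permutation test of X against the 4 large autosomal arms gave p = 0.2 for the share covered, which is the smallest p that 5 arms allow. The same exact permutation test of chromosome 4 against these 4 arms also gave p = 0.2 for the share covered, at a difference of 19.7 percentage points from their mean. The tests over arms were chosen after the values were seen.

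**Figure D1:**
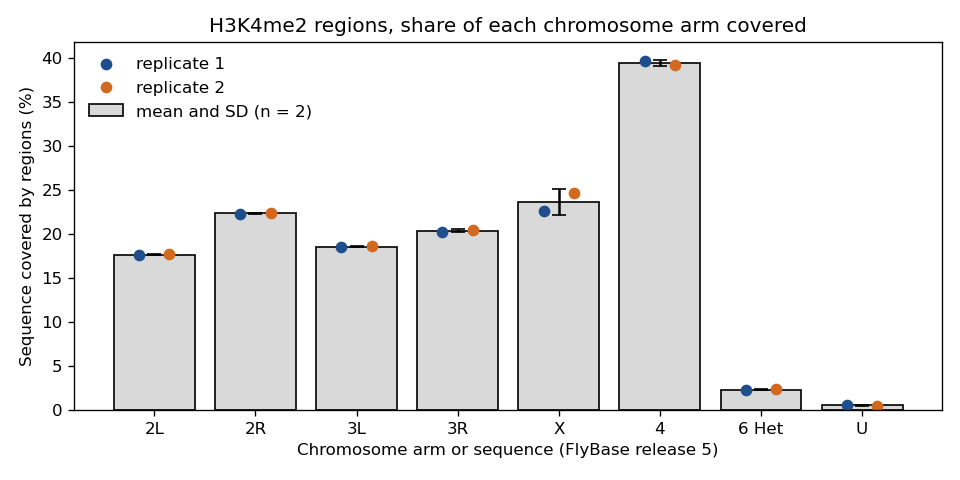
Share of each chromosome arm or sequence covered by H3K4me2 regions, in percent, with bars for the mean of the 2 ChIP replicates, error bars for their SD and points for each replicate. Chromosome 4 stands at 39.5%, the large arms between 17.7% and 23.7%, the 6 heterochromatic sequences at 2.33% and unplaced sequence at 0.524%; X is the arm on which the replicates lie farthest apart.

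Heterochromatic sequence was sparsely covered by regions. The 6 sequences assembled from heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet), which together span 9.28 Mb, were covered to 2.33% ± 0.0458 (SD, n = 2), and the unplaced sequence U to 0.524% ± 0.0443 (SD, n = 2). Within this class XHet was the most marked, at 10.4% ± 0.402 (SD, n = 2) with 6 regions in each replicate. The least marked was YHet or 3RHet, with the order differing between the replicates, and 3RHet was covered to 1.47% ± 0.0344 (SD, n = 2). YHet, the assembled part of the Y chromosome, held 3 regions in each replicate and was covered to 1.52% ± 0.117 (SD, n = 2). How reads that map to many places were treated is not given in the sources used here. The shares are of the full sequence length, so any sequence to which reads could not be mapped counts as uncovered. How much of the low shares this explains was not tested.

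Regions on X and chromosome 4 were wider than those on the large autosomal arms. Median width was 5003 ± 293 bp on chromosome 4 and 4056 ± 56.2 bp on X, against 3584 ± 1.41 bp on the 4 large autosomal arms together (SD, n = 2). In replicate 1, 14.1% of X regions (exact 95% binomial interval 11.9 to 16.5%) were at least 10 kb wide, and in replicate 2 the share was 18.7% (16.2 to 21.5%). On the 4 large autosomal arms together the share was 7.07% (6.30 to 7.90%) in replicate 1 and 7.35% (6.57 to 8.19%) in replicate 2. Chromosome 4 had 13 such regions among 74 in replicate 1 (17.6%, interval 9.70 to 28.2%) and 14 among 75 in replicate 2 (18.7%, interval 10.6 to 29.3%). The spacing of X regions, 39.7 ± 0.0946 (SD, n = 2) per Mb, lay inside the range of the autosomal arms (38.3 to 48.9 per Mb). An exact two-sided permutation test over the 5 large arms gave p = 0.2 for the share of wide regions and for median width, again the smallest possible, and p = 0.8 for regions per Mb.

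**Figure D2:**
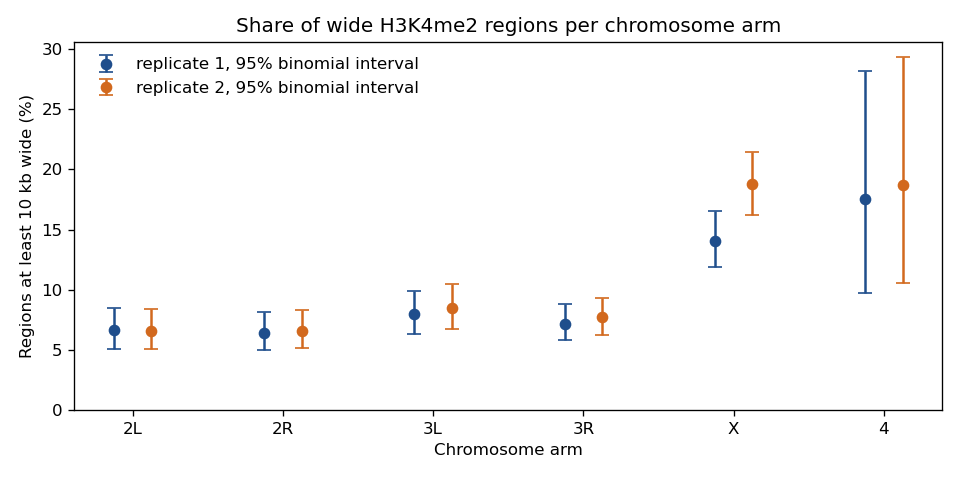
Share of regions at least 10 kb wide on each chromosome arm, in percent, for the 2 ChIP replicates, with exact 95% binomial intervals. X lies at 14.1% in replicate 1 and 18.7% in replicate 2, above the 4 large autosomal arms in both replicates, whose highest value is 8.47%.

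Of the 10 widest regions among those that paired singly between the replicates, 7 lay on X and 1 each on 4, 2L and 3L. Positions are on FlyBase release 5 and are those of replicate 1. The widest was on X at 1765629 to 1796924, with a mean width of 31.2 ± 0.0806 kb (SD, n = 2). X 9035953 to 9065845 and X 21202198 to 21232238 followed, with mean widths of 30.2 ± 0.491 kb and 30.2 ± 0.270 kb (SD, n = 2). The next were X 2518178 to 2546797 at 29.1 ± 0.694 kb and X 19521102 to 19549763 at 29.0 ± 0.515 kb (SD, n = 2). The chromosome 4 region at 133745 to 162314 had a mean width of 28.2 ± 0.463 kb, the 2L region at 922546 to 948320 one of 26.4 ± 0.885 kb, and the 3L region at 9439303 to 9464902 one of 26.3 ± 0.928 kb (SD, n = 2). The last X members of this group were at 19379441 to 19405164 (26.3 ± 0.799 kb, SD, n = 2) and at 19624439 to 19649999 (25.9 ± 0.474 kb, SD, n = 2). Scores differed among these regions. The authors' score was 2.23 and 2.19 in replicates 1 and 2 for the widest X region, but 1.27 and 1.31 for the chromosome 4 region and 1.13 and 1.13 for the 2L region. The widest region of the 2 replicate lists, chosen after the values were seen, was a replicate 2 region of 54.5 kb on X at 15590794 to 15645311. Replicate 1 had 2 regions there, of 21.3 and 32.3 kb.

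The second comparison asks whether both ChIP replicates marked the same places. They did for most regions. Of the replicate 1 regions, 95.8% (exact 95% binomial interval 95.2 to 96.4%) overlapped a replicate 2 region by at least 1 bp, and 94.2% (93.5 to 94.8%) of replicate 2 regions overlapped a replicate 1 region. The shared sequence was 89.6% of the sequence covered in either replicate. When the replicate 1 regions were placed at random within their arms, the shared sequence averaged 11.7% and did not exceed 12.6% in 1000 placements. The share of regions overlapping the other list then averaged 34.5% for replicate 1 (at most 36.1%) and 37.4% for replicate 2 (at most 39.5%), below the observed shares in each placement (one-sided permutation p = 0.001 for each of the 3 measures, the smallest these placements can give). Region ends lay close together, with a median distance of 76 bp between starts and 73 bp between ends for the 4321 pairs of regions that overlapped only each other. Across these pairs, the scores of the replicates correlated with Pearson's r = 0.97 and Spearman's rho = 0.97 (two-sided permutation p = 1e-05 for both, the smallest 100000 pairings can give, and 1e-05 after Benjamini-Hochberg adjustment over the 2 relations). This correlation is across regions, which are not independent replicates. It held within X (r = 0.96, 647 pairs) and within the 4 large autosomal arms (r = 0.98, 3548 pairs).

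Regions found in only 1 replicate were narrow and scored low. There were 214 in replicate 1, with a median width of 1528 bp and a median score of 0.56, against 3805 bp and 1.37 for its shared regions. There were 298 in replicate 2, with a median width of 1610 bp and a median score of 0.54, against 3834 bp and 1.32 for its shared regions. X held 109 of the 298 regions found only in replicate 2 (36.6%, exact 95% binomial interval 31.1 to 42.3%), but 17.4% of all replicate 2 regions (16.4 to 18.5%). In replicate 1, X held 31 of the 214 (14.5%, interval 10.1 to 19.9%). The 3 highest-scoring regions of this kind were on U at 7869533 to 7870932 in replicate 1 (score 1.78), on 2L at 15676768 to 15678249 in replicate 2 (score 1.18) and on U at 9269460 to 9271466 in replicate 1 (score 1.06).

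The difference between the replicates was not the same on X as on the large autosomal arms, in the score of paired regions and in the share of sequence covered. The score of replicate 2 minus that of replicate 1 had a median over paired regions of -0.06 on the 4 large autosomal arms (quartiles -0.13 and 0.01) and of 0.04 on X (quartiles -0.05 and 0.13). Because the score is not defined in the sources used here, only this contrast with the autosomal regions of the same lists is used. The difference between X and the autosomal arms was 0.10 (two-sided permutation p = 1e-04 over region pairs, the smallest 10000 permutations can give). Of X pairs 61.4% scored higher in replicate 2, against 29.0% of autosomal pairs. The pairs took in 647 of the 888 X regions of replicate 1 and 3548 of its 4089 autosomal regions. Over all regions, the median score fell from replicate 1 to replicate 2 on X (1.33 to 1.27) as on the autosomal arms (1.34 to 1.28). The score contrast was thus seen in paired regions only, but the medians over all regions do not test it, as they are over unlike sets. Regions found in only 1 replicate, which scored low, were 12.2% of the X regions of replicate 2 and 3.49% of those of replicate 1. By autosomal arm they were 3.11 to 5.46% in replicate 2 and 3.80 to 4.71% in replicate 1. In windows of 1 Mb, the share covered was higher in replicate 2 in 23 of 23 X windows and in 55 of 99 autosomal windows, the shorter last window of each arm included. The mean gain was 2.06 percentage points (SD 0.876 over windows) on X and 0.0972 (SD 0.412) on the autosomal arms (two-sided permutation p = 1e-05, the smallest 100000 permutations can give). Neighbouring windows and regions are not independent, and each replicate is a single library pair, so these tests, chosen after the values were seen, compare the 2 lists. XHet moved with X, with 4 of 6 pairs higher in replicate 2 and a median difference of 0.06, but so did the 2 pairs on the autosomal sequence 2LHet, with a median difference of 0.08. The 3 YHet pairs, which are neighbours, were all lower in replicate 2, with differences from -0.55 to -0.22. The 19 pairs on U had a median difference of -0.23.

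**Figure D3:**
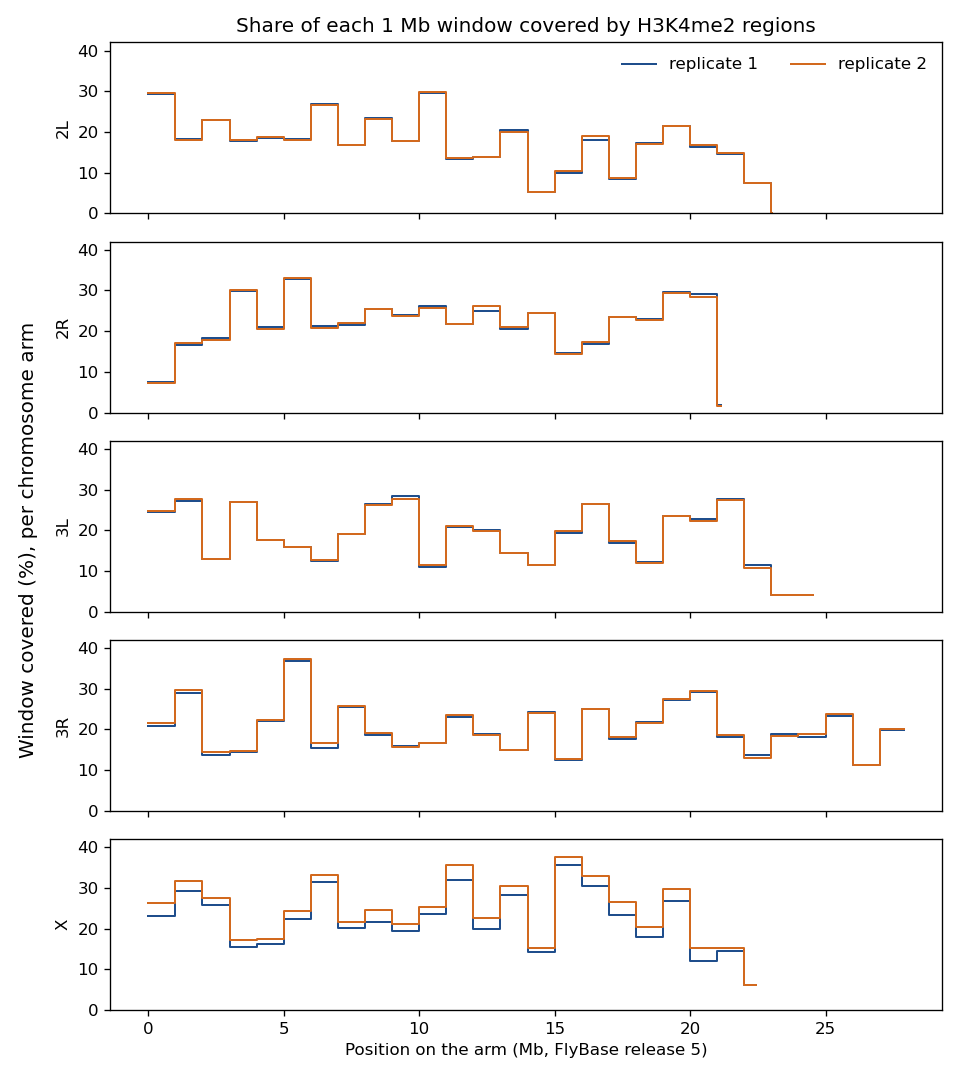
Share of each 1 Mb window covered by H3K4me2 regions, in percent, along the 5 large chromosome arms, with a line for each ChIP replicate and a shorter last window on each arm. On X replicate 2 lies above replicate 1 in 23 of 23 windows, and on the autosomal arms in 55 of 99.

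**Figure D4:**
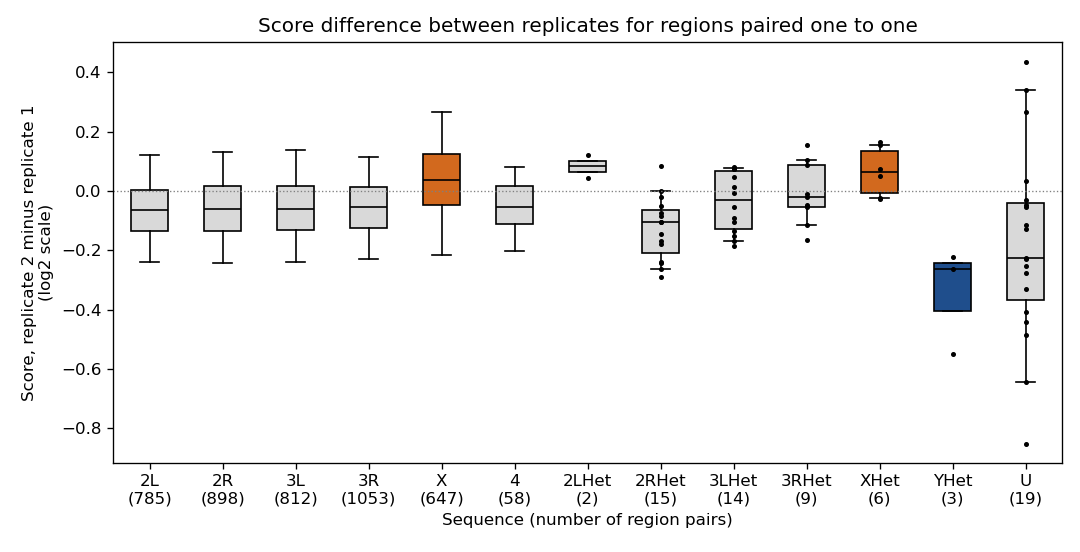
Score of replicate 2 minus score of replicate 1 for regions paired between the replicates, by sequence, with boxes for the median and quartiles, whiskers from the 5th to the 95th percentile and points where there are fewer than 20 pairs. X, with a median of 0.04, lies above the large autosomal arms, whose medians lie between -0.06 and -0.05, and the 3 YHet pairs lie below 0.

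The third comparison sets the list for both replicates together beside the separate lists. It held 5559 regions over 28.4 Mb, and 81.7% of them (exact 95% binomial interval 80.7 to 82.7%) overlapped a region in both replicates. A further 184 overlapped replicate 1 alone and 265 replicate 2 alone, and 567 (10.2%, interval 9.42 to 11.03%) overlapped neither. Every replicate 1 region was represented in it, as were 5118 of the 5125 replicate 2 regions. The regions in neither replicate had a median width of 1315 bp and a median score of 0.38, against 4441 bp and 1.30 for those in both. X held 144 of the 567 (25.4%) and 17.9% of all combined regions, and 3R held 110 (19.4%) and 23.2% of all combined regions, a difference that was not tested. The 3 highest scores of this group were those of very short regions, on 3L at 8013932 to 8014940 (score 3.29), on U at 7586352 to 7587374 (score 3.16) and on 3RHet at 1720260 to 1721260 (score 2.87). These 3 were chosen after the values were seen.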

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

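Replicate overlap and score correlation kept their direction and their side of the threshold under each alternative run. The share of replicate 1 regions found in replicate 2 ranged from 90.3% (reciprocal overlap of 50%) to 96.3% (regions under 1000 bp apart merged), and the highest chance share was 45.1%, under circular shifts. The correlation of scores was 0.93 for scores divided by width. Of the combined list, 78.4% was in both replicates and 11.3% in neither at a reciprocal overlap of 50%. For the higher-scoring 50% of each list the shares were 83.5% and 7.70%. Each list was cut there at its own median score (1.11 combined, 1.33 replicate 1, 1.27 replicate 2). A combined region could thus count as in neither although a replicate region below its cut overlapped it. Of the 567 combined regions that overlapped neither full list, 515 scored below 0.53 and so fell below the combined cut. The share covered necessarily changes with the regions kept. On the combined list it was 19.8% for 2L, 25.02% for 2R, 20.8% for 3L, 22.8% for 3R, 27.3% for X, 44.3% for chromosome 4, 2.72% for the 6 heterochromatic sequences and 0.683% for U. With the higher-scoring 50% of each list it was 11.2% for 2L, 15.1% for 2R, 12.5% for 3L, 13.8% for 3R, 17.6% for X, 22.9% for chromosome 4, 1.00% for the heterochromatic sequences and 0.205% for U. Chromosome 4 stayed first and X second in these settings and in each replicate alone. The X score difference, added after the data were seen, was 0.08 to 0.10 under its 3 alternatives. No paired analysis was possible because no values of the input libraries were used here. The planned annotation of covered sequence, the marked genes and the gene lists, with their alternatives, were not run for want of an annotation of the same build. Read depth is unknown here, so what it limits was not tested.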

Other observations

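The tests in this part were chosen after the results were seen. Along the large arms the covered share of full 1 Mb windows ranged from 4.14% to 37.0% (median 20.8% over 117 windows, mean of the 2 replicates). The fullest window was 3R from 5 to 6 Mb, with 36.8% covered in replicate 1 and 37.3% in replicate 2. The X window from 15 to 16 Mb followed, with 35.8% and 37.7%. The emptiest were 3L from 23 to 24 Mb (4.08% and 4.20%) and 2L from 14 to 15 Mb (5.29% and 5.31%). The last Mb of the assembled arm on the side of the centromere was poorly covered on 4 of the 5 large arms. It held 2.96% on 3L in replicate 1 against 19.2% on the rest of that arm, 7.42% on 2R against 23.1%, 7.53% on 2L against 18.1% and 9.37% on X against 23.2%. On 3R this end was covered like the rest of the arm, at 20.96% against 20.2%. Replicate 2 gave the same order within each arm.

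H3K4me2 regions were clustered, with long stretches that held none in either replicate. There were 168 stretches of at least 100 kb on the 6 arms, against a mean of 25.5 and a highest count of 40 in 1000 random placements (one-sided permutation p = 0.001, the smallest these placements can give). The placements used whole arms, including the poorly covered ends near the centromere and any sequence to which reads could not be mapped. How much of the excess lies in such sequence was not tested. The longest was on 3L from 23335794 to 23707824, at 372 kb. X 21501621 to 21844670 (343 kb), 3R 1834959 to 2169573 (335 kb) and 3R 12481500 to 12810730 (329 kb) followed. The last of these lies far from the centromere, and the combined list placed 2 regions inside it. Other mid-arm stretches of this kind were 2L 14689998 to 14969193 (279 kb), with 1 region of the combined list inside it, and 2R 15720164 to 15998335 (278 kb), with none. The longest stretch in the random placements was 326 kb, longer than both of these.

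The score difference of X between the replicates, 0.10 over paired regions against the autosomal arms, was spread along X. The median difference lay above the autosomal median in 23 of 23 X windows of 1 Mb. A median over 647 pairs cannot come from a few X regions, so the windows show spread and are no separate test of that. Matching on score level and width did not remove the difference. It was 0.10 (0.0977, SE 0.00569) against autosomal pairs matched in 10 bins of score and 3 of width. Width was thus matched coarsely, but among regions under 10 kb the difference was also 0.10 (0.0965). Neighbouring pairs are not independent, so the SE may be too small. A candidate explanation is a higher share of female flies in the ChIP, relative to its input, in replicate 2 than in replicate 1. If the score, which is not defined in the sources used here, measures ChIP relative to input, such a share would raise X and XHet and lower YHet in replicate 2. YHet pairs fell by 0.288 relative to the autosomal heterochromatic pairs (3 against 40 pairs, two-sided exact permutation p = 0.00194) and XHet pairs rose by 0.123 (6 pairs, two-sided exact permutation p = 0.0129). These values do not decide it, because autosomal sequence moved as far as XHet (2LHet, median 0.08, 2 of 2 pairs higher) and 2RHet the other way (median -0.11), the 3 YHet regions are neighbours, and pairs on U had a median of -0.23. A difference in H3K4me2 itself on the X of the flies collected, and a difference in base composition between the libraries, were not tested and stay open.

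The combined list held 567 regions that overlapped neither replicate list. Of these, 47.6% were narrower than the narrowest replicate region and 297 were not. These counts cannot decide what share a shorter minimum width would explain, because widths differ between the lists. The median was 1823 bp for combined regions that overlapped replicate 1 alone, and 1528 bp for regions found only in replicate 1. Most scored low, with 515 of the 567, and 280 of the 297 (94.3%), below the lower quartile of the combined list (0.53). Weaker enrichment than in combined regions found in exactly 1 replicate was not shown, since the median scores of the 567 and of those 449 regions differed by 0.000679 (two-sided permutation p = 0.889, and 0.889 after Benjamini-Hochberg adjustment over 2 comparisons). Among regions at least as wide as the narrowest replicate region the difference was -0.01 (297 against 428 regions, two-sided permutation p = 0.0418, adjusted p = 0.0836). The 567 regions were narrower, with a median width of 1315 bp. Combined regions that overlapped replicate 1 alone or replicate 2 alone had medians of 1823 and 1867 bp. Of the 567, 297 were at least as wide as the narrowest replicate region, against 428 of the 449. This difference in width was not tested. Whether anything besides width sets the 567 apart stays open, and how the authors combined the replicates is not given in the sources used here.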
